A study of Mus musculus with 4 samples.

How the data were processed

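RNA was extracted with Trizol from flash-frozen spleen cell suspensions, and 2 µg of total RNA per sample went into TruSeq RNA v2 libraries, per the labels' protocols. This kit does not mark the strand of the transcript. Libraries were sequenced as 50 bp single-end reads on an Illumina HiSeq instrument, per the series design. The labels describe the 2 samples of each group as biological replicates.

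The authors deposited 1 table with an FPKM value (fragments scaled by transcript length and by library size) for each of 4 libraries, per the file headers. Bowtie2 2.1.0, TopHat2 2.0.9, Cufflinks and Cuffdiff 2.1.1 and the mm10 build are named in the submitters' processing notes, which give no settings. Per the file headers, the deposited table also holds a group FPKM, a log2 fold change of vcS5 over wild type, a p-value and a q-value from the authors' comparison. The group FPKM differed by over 0.1% from the mean of the library values in 5 rows. Every row has a mean FPKM above 1, and row ranks run to 23180, so the table used here is part of a longer one. The submitters' filter is not given in the sources used here.

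FPKM is scaled to the library and the transcript length, so read numbers are lost. Low values fell on whole-read steps, and the worth of 1 read in wild-type replicate 1 was 0.847 of that in replicate 2, 0.900 of that in vcS5 replicate 1 and 0.831 of that in vcS5 replicate 2. Relative depth on that scale therefore differed little, while absolute depth stays unknown and no counting interval is given. FPKM summed to 1349925 and 1469133 in wild type and to 1239862 and 1219374 in vcS5. The 10 most abundant rows took 51.5% and 50.1% of that sum in wild type and 43.3% and 37.6% in vcS5. Were values scaled to the mapped total alone, this would move all other FPKM values of a library. Median FPKM was 12.16 and 12.49 in wild type and 12.22 and 12.58 in vcS5. The median change over all rows was 0.001 on the log2 scale, so no shift of the rows as a whole is seen. Exact zeros occurred in 87 rows, always in both libraries of a group, 54 in wild type and 33 in vcS5, and 78 of them passed the test. No fold is given against a group listed at 0.

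Rows were named by the deposited symbol, otherwise through the Ensembl identifier in GENCODE vM21, and 12571 of 12810 rows with an identifier matched. For 1416 rows no identifier was given, and they are called unannotated loci. In 7 rows the symbol and the locus disagreed, 424 rows merge several genes, and 4322 rows share a locus with another row. Overlapping and antisense genes cannot be told apart without strand. Coordinates are 1-based on mm10, the build that GENCODE vM21 (GRCm38) annotates.

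Values were transformed as log2(FPKM + 1), and fold changes on that scale understate changes of low rows. The planned filter of a mean FPKM of at least 1 removed 0 rows. The comparison used limma 3.58.1 in R 4.3.3 with the variance trend and no covariates on 14226 rows and all 4 libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The prior had 3.17 and the residual 2 degrees of freedom. SEs are the moderated ones of limma. Folds quoted are ratios of mean FPKM. Branches planned for raw counts or for pooled values only did not apply.

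Before the data were examined, 32 gene lists with 516 entries were fixed from textbook knowledge. Of these entries 454 were measured, and 30 lists had at least 4 members. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over lists. With an estimated correlation camera rests on the 2 residual degrees of freedom, which leaves it little power. Named genes followed a rule fixed at the same time. It takes Stat5a and Stat5b, the 12 largest rises and 12 largest falls among rows past the threshold with at least 5 FPKM in the higher group and no overlap between groups, up to 4 members per list, and the abundant constant region and haemoglobin genes. Receptor segments, Gm and Rik symbols and small RNAs were left out of the ranking by that rule. Rows without a symbol and rows with a 0 were left out as well, a choice made after the data were seen. Some genes that this rule names are not reported here. Hopx, Hopxos and Stat3 were looked up after their neighbours were seen.

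The scripts were tested on simulated data for the vcS5 comparison, with 200 of 14226 rows changed in each of 20 runs. Changed rows and list members were drawn only from rows with a mean FPKM of at least 5. Recovery of lower rows was therefore not simulated. Recovery was 3.6% at 1.5-fold, 63.1% at 2-fold, 97.7% at 4-fold and 99.5% at 8-fold. Unchanged rows made up 10.3% of the simulated calls, above the 5% aimed at. A list of 15 rows shifted by 1 on the log2 scale was found in 20 of 20 runs, and an unshifted list was called in 0 runs. Lists with correlated members were not simulated, while the estimated correlation of neutrophil and granulocyte markers was 0.78. These runs therefore do not show how often camera calls unshifted lists of correlated genes. The data had 1241 calls against 200 changed rows per run, so the recovery and the share of unchanged rows may differ there.

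Alternatives were pseudocounts of 0.1 and 0.01, a filter at a mean FPKM of 5, the replicate number as a block, leaving out each library, median centring, quantile normalization, no variance trend, a threshold of 0.01, a minimum of 2-fold, and leaving out receptor segments. Added after the data were seen were protein-coding rows only, leaving out rows with a 0, and the q-values of the authors' deposited table. Figures were drawn with matplotlib 3.10.9.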

Results

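Gene expression was measured by RNA sequencing in splenocytes, the mixed cell suspension obtained from a whole spleen, of C57BL/6N mice. There were 2 wild-type libraries and 2 libraries from transgenic mice designated vcS5. The series title names an activating mutation in STAT5 and peripheral T cell lymphoma. STAT5, encoded by the neighbouring genes Stat5a and Stat5b, is the transcription factor that carries signals from interleukin 2, 7 and 15 receptors into the nucleus. The comparison of vcS5 with wild type therefore asks how the spleen transcriptome differs in mice carrying this transgene. The deposited table gave FPKM for 14226 rows per library, with median FPKM of 12.16 and 12.49 in wild type and 12.22 and 12.58 in vcS5. The absolute number of reads behind each library is unknown from the values. Across rows, Pearson's r of the log2 values was 0.978 between the libraries of each group and 0.918 to 0.929 between libraries of different groups, where rows are not independent replicates.

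Stat5a was 7.39-fold higher in vcS5 than in wild type, while no change of Stat5b was detected. Stat5a (mm10 chromosome 11, 100859351 to 100885169, plus strand) had 15.4 ± 2.23 FPKM in wild type (SD, n = 2) and 114 ± 12.6 FPKM in vcS5 (SD, n = 2). Its log2 change was 2.81 (SE 0.168), with an adjusted p of 0.00241 by limma. Stat5b (chromosome 11, 100780731 to 100850724, minus strand) had 24.3 ± 3.20 and 23.9 ± 0.823 FPKM, a log2 change of -0.01 (SE 0.152, adjusted p = 0.971 by limma). Stat5a and Stat5b are close paralogs that can share reads, and the table does not separate a transgene from the endogenous gene. Without vcS5 replicate 2 the log2 change of Stat5a was 2.70, with an adjusted p of 0.0532 by limma. The Stat5a row shares its locus with a row for Stat3, which had 106 ± 9.84 FPKM in wild type and 97.6 ± 3.69 FPKM in vcS5 (SD, n = 2), and the library kit does not record strand.

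Across the table, 1241 rows passed the test, of which 653 were higher and 588 lower in vcS5. Among 11053 protein-coding rows, 469 were higher and 431 lower. All 24 immunoglobulin segment rows that passed, of 192 measured, were lower. Of 89 T cell receptor segment rows, 23 were higher and 3 lower. Among unannotated loci, 97 were higher and 54 lower, and among small noncoding RNAs 34 moved each way. The remaining calls were 27 higher and 31 lower rows of other noncoding genes or pseudogenes, and 3 higher and 11 lower rows whose identifiers were not in the reference. An unadjusted p under 0.05 was reached by 3595 rows. The count fell to 160 without wild type replicate 1, 245 without wild type replicate 2, 94 without vcS5 replicate 1 and 71 without vcS5 replicate 2. Of 107 genes past the test that the naming rule takes or that were looked up, 12 kept their call with each library left out in turn, among them Gzmm, Cd163l1, Il18r1, Klra8 and Ncr1.

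Among genes ranked by the naming rule, which leaves out receptor segments, rows without a symbol and rows with a 0, the largest rises included granzymes, chemokine and receptor genes. Gzmm, which encodes a granzyme of cytotoxic lymphocytes, rose 44.0-fold, from 2.29 ± 0.698 to 101 ± 24.2 FPKM (SD, n = 2 each; log2 change 4.95, SE 0.241, adjusted p = 0.00123 by limma). Gzmb, the granzyme B gene, rose 12.3-fold, from 7.79 ± 2.93 to 96.1 ± 11.1 FPKM. Ccl5, a chemokine of memory and effector CD8 T cells, rose 9.41-fold, from 240 ± 66.9 to 2257 ± 176 FPKM. Il18r1, a subunit of the interleukin 18 receptor, rose 8.30-fold, from 16.0 ± 0.0724 to 133 ± 4.70 FPKM. Cd163l1, a scavenger receptor gene of the WC1 family, had a log2 change of 4.14 (SE 0.219). The log2 changes of Drc1, Gpr15, Myo6, F2r, Lpin1 and Tmem37 were 3.98, 3.68, 3.57, 3.38, 3.01 and 2.98, with SEs from 0.164 to 0.263. The highest ranked row (chromosome 5, 77086443 to 77115161) carries the symbol Pax9 in the deposited table, but the reference annotates Hopx and its antisense transcript Hopxos there. That row rose from 0.547 ± 0.0213 to 50.0 ± 19.1 FPKM, and the separate Hopx row from 20.7 ± 2.17 to 63.7 ± 3.62 FPKM.

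Of the same ranked genes, Ncr1, the gene of the natural killer cell receptor NKp46, fell most. It went from 14.4 ± 0.989 to 0.705 ± 0.0994 FPKM (SD, n = 2 each), 20.4-fold lower in vcS5 (log2 change -3.17, SE 0.165, adjusted p = 0.00161 by limma). Clec5a, Fcnb and Trem3 had log2 changes of -1.93, -1.75 and -1.64, and differed between the wild-type libraries, with SDs of 2.39, 4.07 and 2.82 FPKM around means of 5.23, 7.60 and 6.34. Fcnb lost its call with quantile normalization (adjusted p = 0.0528 by limma) and without the variance trend (0.0503). Cr2, the complement receptor of mature B cells, fell from 226 ± 3.91 to 71.8 ± 0.0926 FPKM. Oasl1, S1pr3 and Anxa1 changed by -1.95, -1.92 and -1.84. Anxa1 also differed between the wild-type libraries, at 158 and 91.5 FPKM, and changed by -1.45 without wild type replicate 1. Ccbp2, Plaur, Myof and Dusp3 changed by -1.72, -1.70, -1.66 and -1.64.

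T cell genes were higher in vcS5, most of all those of CD8 T cells. Of 18 pan T cell markers, 12 rose and none fell, with a median log2 change of 1.25, and 17 rose when adjusted over the list alone. Thy1, Cd3d and Ubash3a had log2 changes of 2.15, 1.66 and 1.66. Of 10 CD8 T cell markers, 8 rose and none fell, with a median of 2.16, and all 10 rose when adjusted over the list alone. Cd8a, encoding the CD8 alpha chain, had 51.1 and 62.9 FPKM in wild type and 391 and 445 FPKM in vcS5 (log2 change 2.86, SE 0.174, adjusted p = 0.00259 by limma), and Cd8b1 from 89.2 ± 21.2 to 613 ± 66.4 FPKM. Nkg7 had a log2 change of 2.38. By camera the adjusted p was 1.81e-11 for the pan T and 2.02e-10 for the CD8 list, against an adjusted p of 0.433 for each with an estimated correlation. Cd8a lost its call without vcS5 replicate 2, with an adjusted p of 0.057 by limma.

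**Figure D1:**
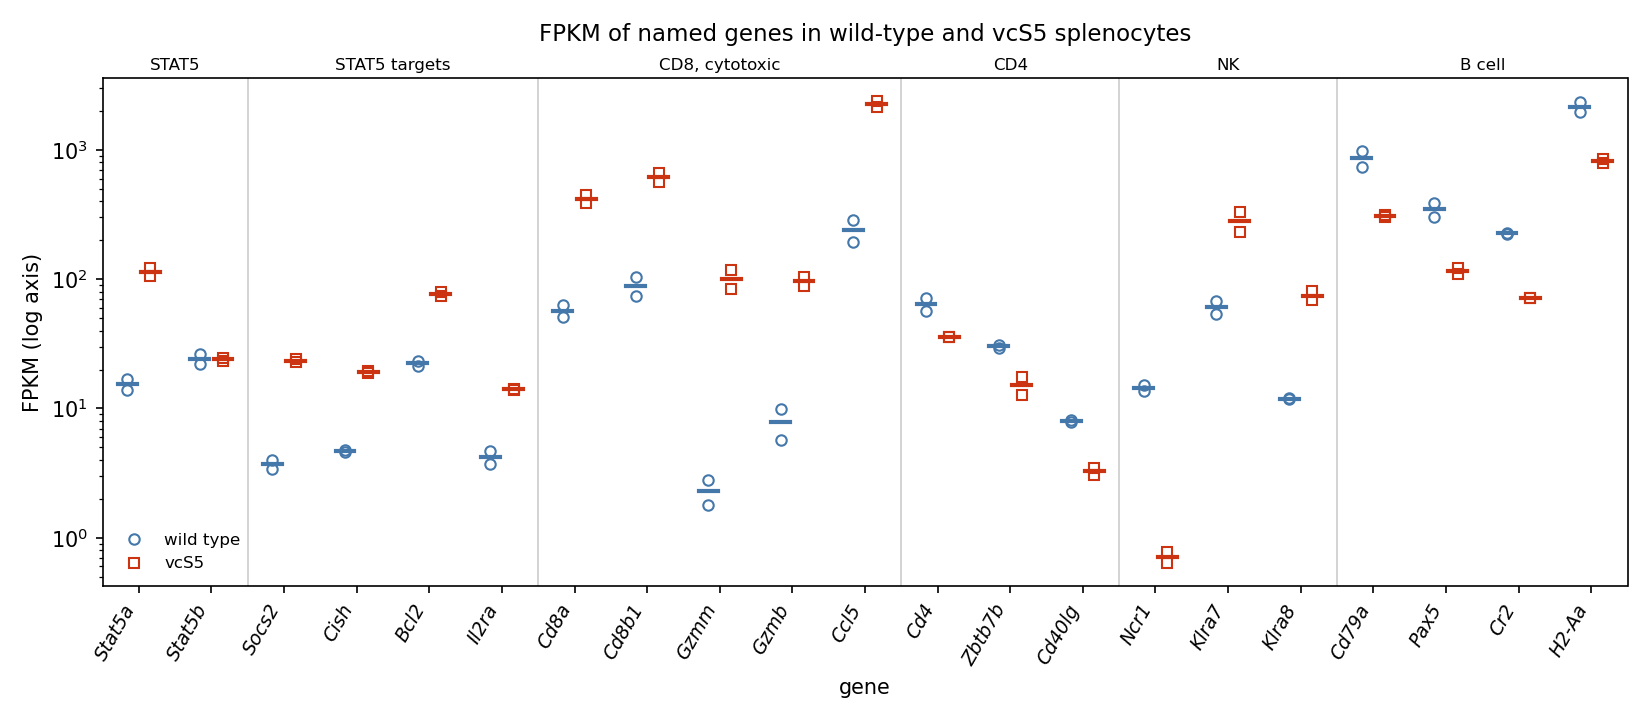
FPKM (log axis) of 21 named genes in the 2 wild-type libraries (blue circles) and the 2 vcS5 libraries (red squares), with bars at the group means. Stat5a, the CD8 and cytotoxic genes lay higher in both vcS5 libraries, with Stat5a at 15.4 and 114 FPKM on average, and the CD4, B cell and Ncr1 points lay lower.

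CD4 and regulatory T cell markers did not follow the pan T cell markers. Of 9 measured, 1 rose and 3 fell, with a median of -0.64 (camera adjusted p = 0.0195, and adjusted p = 0.433 with an estimated correlation). Adjusted over the list alone, 1 rose and 4 fell. Cd4 fell from 63.9 ± 10.1 to 35.8 ± 0.243 FPKM (log2 change -0.81, SE 0.16, adjusted p = 0.0445 by limma). Zbtb7b, the transcription factor that directs CD4 lineage choice, changed by -0.97 and Cd40lg by -1.08. The member that rose was Il2ra, the high-affinity interleukin 2 receptor chain, with 1.54. Cd4 and Zbtb7b lost their calls in the fit without the variance trend, with adjusted p-values of 0.0582 and 0.0528 by limma, and the list lost its call without vcS5 replicate 2 (camera adjusted p = 0.0996, median -0.25).

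Genes of cytotoxic effector cells share Eomes, Gzmk, Nkg7 and Ccl5 with the CD8 list. Of 22 measured, 13 rose and 1 fell, with a median of 1.45 (camera adjusted p = 1.12e-07, and adjusted p = 0.433 with an estimated correlation). With p-values adjusted over the list alone, 15 rose and 3 fell. Of the 18 members outside the CD8 list, 10 rose and 1 fell, with a median of 1.37. The leading members were Gzmm, Gzmb, Ccl5 and Nkg7. Natural killer cell markers moved both ways, with 6 of 13 higher and 4 lower, a median of -0.11 and a camera adjusted p of 0.482. In all, 6 rose and 5 fell when adjusted over the list alone. Klra8, Klra7 and Eomes had log2 changes of 2.55, 2.18 and 2.20, and Ncr1 of -3.17. Klra8 and Klra7 belong to the Ly49 receptor family, whose members are alike in sequence, and their rows share 1 locus with others, so their separate values are uncertain.

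Among T cell state lists, naive T cell genes had 4 of 12 members higher and none lower, with a median of 0.20 (camera adjusted p = 0.01, and adjusted p = 0.584 with an estimated correlation). Il7r, the interleukin 7 receptor, rose from 40.1 ± 1.23 to 187 ± 17.7 FPKM, and Dapl1, Tcf7 and Satb1 had log2 changes of 1.93, 1.21 and 1.03. When adjusted over the list alone, 5 rose. Dapl1 lost its call without the variance trend (adjusted p = 0.0519 by limma). The list lost its call without wild type replicate 1 (camera adjusted p = 0.0753, median 0.07) and without vcS5 replicate 1 (0.0532), and its median was 0.39 without wild type replicate 2. Inhibitory receptor and exhaustion genes had 1 of 12 lower, Cd244 at -1.08, and none higher, with a median of -0.59 (camera adjusted p = 0.0327, and adjusted p = 0.433 with an estimated correlation). Adjusted over the list alone, 2 rose and 5 fell. That call was lost without wild type replicate 1 (camera adjusted p = 0.0987, median -0.36), without vcS5 replicate 2 (0.167, median -0.38) and with the filter at a mean FPKM of 5 (0.083). Memory and activation genes did not pass the list test (camera adjusted p = 0.142, median 0.08), with 5 of 14 higher and 2 lower, and 6 and 2 when adjusted over the list alone. Among them Ly6c2, Il2rb and Cxcr3 rose by 2.32, 2.13 and 1.94 on the log2 scale, the Ly6c2 row lying in a locus it shares with related genes.

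STAT5 target genes had 11 of 24 members higher and 1 lower, with a median of 0.62 (camera adjusted p = 2.66e-04, and adjusted p = 0.433 with an estimated correlation). With p-values adjusted over the list alone, 15 rose and 3 fell. Socs2, a feedback inhibitor of cytokine signalling, rose 6.28-fold, from 3.72 ± 0.415 to 23.3 ± 0.920 FPKM (SD, n = 2 each). Cish, another of these inhibitors, rose 4.06-fold, from 4.71 ± 0.0817 to 19.1 ± 0.567 FPKM. Bcl2, which blocks apoptosis, rose 3.42-fold, from 22.4 ± 1.35 to 76.6 ± 3.49 FPKM. Bcl6, a transcriptional repressor that STAT5 is known to repress, fell from 28.4 ± 1.92 to 12.4 ± 0.403 FPKM. Gzmb belongs to this list and to the cytotoxic list. These rises stood beside medians of 2.16 for CD8 T cell and -1.38 for B cell markers.

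Of 14 JAK and STAT genes, Stat5a, Stat4 (log2 change 1.06) and Jak1 (0.74) rose and none fell, and the list did not pass (camera adjusted p = 0.363, median 0.01). The 3 rises were also those adjusted over the list alone, and Jak1 lost its call with the filter at a mean FPKM of 5 (adjusted p = 0.0501 by limma) and without the variance trend (0.0506). Common gamma chain cytokine receptor genes did not pass as a list (camera adjusted p = 0.073, median 0.27), with 4 of 10 higher and 1 lower, and 5 and 1 when adjusted over the list alone. With the filter at a mean FPKM of 5 this list passed as higher, with a camera adjusted p of 0.02 and a median of 0.99 over 8 members, while the median ran from 0.11 without wild type replicate 1 to 0.44 without wild type replicate 2. Il7r rose by 2.19 and Il9r fell by 1.58 on the log2 scale. Apoptosis regulators had 6 of 18 higher and 1 lower, with a median of 0.19 (camera adjusted p = 0.0363, and adjusted p = 0.433 with an estimated correlation). In all, 7 rose and 2 fell when adjusted over the list alone. Their risers act in both directions, with Fasl and Bbc3, which promote cell death, at 2.30 and 2.15, and Bcl2 and Bcl2l1, which oppose it, at 1.73 and 1.35. This call was lost without wild type replicate 2 (camera adjusted p = 0.0528) and without vcS5 replicate 1 (0.0572, median 0.40), and the median was 0.08 without vcS5 replicate 2.

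No gene of the cell division or DNA replication lists passed the test by limma, with 2 and 3 genes at an unadjusted p under 0.05 and 0 in each at a q under 0.05 in the authors' deposited table. Of 22 cell division genes the median was -0.05 (camera adjusted p = 0.363), with Mki67 at 25.8 ± 0.564 and 24.8 ± 6.95 FPKM and Top2a at 37.8 ± 17.1 and 37.4 ± 3.47 FPKM. Without wild type replicate 2 the cell division list passed as lower, with a camera adjusted p of 0.0363 and a median of -0.14. Of 21 DNA replication genes the median was 0.11 (camera adjusted p = 0.218), with log2 changes of 0.22 for Mcm2 and 0.22 for Mcm3. In both lists 0 genes passed when adjusted over the list alone. Glycolysis genes had 1 of 15 higher, Pfkp at 0.82, and none lower (median 0.18, camera adjusted p = 0.142), and 1 when adjusted over the list alone. Of 19 tumour suppressor and oncogene genes, Cdkn1a (1.16) and Fyn (0.97) rose and Rb1 (-0.96) and Id3 (-0.80) fell, the same numbers as when adjusted over the list alone (median 0.09, camera adjusted p = 0.549). Rb1 and Id3 lost their calls without the variance trend (adjusted p = 0.058 and 0.0519 by limma).

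B cell genes were lower in vcS5. Of 17 B cell markers, 15 fell and none rose, with a median log2 change of -1.38 (camera adjusted p = 8.78e-13, and adjusted p = 0.433 with an estimated correlation). When adjusted over the list alone, 16 fell. Pax5, the transcription factor of B cell identity, went from 347 ± 61.7 to 116 ± 9.58 FPKM (SD, n = 2 each), Cd79a from 858 ± 181 to 308 ± 5.07 FPKM and Blnk from 126 ± 12.8 to 46.7 ± 2.78 FPKM. Of 13 genes of MHC class II antigen presentation, 11 fell and none rose, with a median of -1.15 (camera adjusted p = 4.32e-09, and adjusted p = 0.433 with an estimated correlation). Adjusted over the list alone, 12 fell. H2-Aa, H2-DMb2, H2-Ab1 and H2-Eb1 had log2 changes of -1.39, -1.37, -1.34 and -1.32.

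Plasma cell markers had 3 of 13 lower and none higher, Irf4, Mzb1 and Tnfrsf13b at -1.28, -1.17 and -1.12, with a median of -0.52 (camera adjusted p = 0.00118, and adjusted p = 0.433 with an estimated correlation), and 3 lower when adjusted over the list alone. Without wild type replicate 1 the plasma cell median was -0.32. Germinal centre genes had 2 of 10 lower, Cxcr5 at -1.22 and Bcl6 at -1.13, with a median of -0.47 (camera adjusted p = 0.00465, and adjusted p = 0.433 with an estimated correlation). With p-values adjusted over the list alone, 1 rose and 3 fell. Among constant region genes, Ighg3 fell from 201 ± 47.7 to 13.9 ± 10.01 FPKM (log2 change -3.93, SE 0.504, adjusted p = 0.0168 by limma), and Trbc2 of the T cell receptor beta chain rose from 148 ± 37.1 to 342 ± 26.6 FPKM (adjusted p = 0.0351 by limma). Igkc, Igha, Ighm, Ighg1, Ighg2b, Ighg2c and Trac did not pass. Igkc had 21300 ± 3011 and 11230 ± 1523 FPKM, Ighm 5389 ± 463 and 4482 ± 2235 FPKM, and Trac 1224 ± 1335 and 1034 ± 842 FPKM. Ighg3 lost its call without wild type replicate 1 (adjusted p = 0.0952 by limma), without wild type replicate 2 (0.079) and without vcS5 replicate 2 (0.0625).

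Of the 18 neutrophil and granulocyte markers, 1 fell, Csf3r at -1.04, with a median of -1.47 (camera adjusted p = 1.27e-06, and adjusted p = 0.44 with an estimated correlation). In all, 9 fell when adjusted over the list alone, 12 members had an unadjusted p under 0.05 by limma, and 16 were lower at a q under 0.05 in the authors' deposited table. Their mean log2 value differed between the wild-type libraries, at 6.23 and 4.71, with 3.84 and 4.06 in vcS5. Without wild type replicate 1 the median was -0.75 with 0 calls, and without wild type replicate 2 it was -2.37 with 10 lower. Monocyte and macrophage markers had 1 of 16 higher, Ccr2 at 1.79, and 1 lower, Lyz2 at -1.34, the same numbers as when adjusted over the list alone, with a median of -0.44 (camera adjusted p = 0.00966, and adjusted p = 0.59 with an estimated correlation). Ccr2 lost its call with quantile normalization (adjusted p = 0.0537 by limma) and without the variance trend (0.0508), and its log2 change ran from 1.29 to 2.30 with 1 library left out. The list call was lost without wild type replicate 1 (camera adjusted p = 0.121) and without vcS5 replicate 1 (0.229, median -0.20), and the median was -0.75 without vcS5 replicate 2. Dendritic cell markers had 2 of 10 lower, Siglech at -1.03 and Ccr9 at -0.91, and 4 when adjusted over the list alone (median -0.56, camera adjusted p = 0.00966, and adjusted p = 0.433 with an estimated correlation). With the filter at a mean FPKM of 5 this call was lost (camera adjusted p = 0.0901).

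Mast cell and basophil markers passed as a list (median -0.85, camera adjusted p = 0.00471, and adjusted p = 0.433 with an estimated correlation) with none of 8 members past the test by limma, also when adjusted over the list alone. By limma 4 had an unadjusted p under 0.05, and 6 were lower at a q under 0.05 in the authors' deposited table. Mcpt8 had 17.5 and 4.54 FPKM in the wild-type libraries and 2.59 and 3.38 FPKM in vcS5, and Fcer1a 2.34 ± 1.39 and 0.730 ± 0.0526 FPKM. The mast cell and basophil median was -0.45 without wild type replicate 1, -1.28 with 2 members lower without wild type replicate 2, and -1.35 and -1.44 at pseudocounts of 0.1 and 0.01. Progenitor markers had 1 of 7 lower, Sox4 at -1.04, and 3 when adjusted over the list alone (median -0.81, camera adjusted p = 0.00465, and adjusted p = 0.433 with an estimated correlation), and their median was -0.46 without wild type replicate 1. Of 18 erythroid markers none passed, also when adjusted over the list alone (median -0.47, camera adjusted p = 0.126), and Hba-a1 had 339 ± 60.1 and 274 ± 187 FPKM and Hba-a2 193 ± 58.1 and 173 ± 125 FPKM. By limma 0 of them had an unadjusted p under 0.05, and 1 was lower at a q under 0.05 in the authors' deposited table. Without vcS5 replicate 2 the erythroid list passed as lower, with a camera adjusted p of 5.69e-07 and a median of -1.16. Of 7 megakaryocyte and platelet markers, Itgb3 rose by 1.43 on the log2 scale, and adjusted over the list alone 1 rose and 2 fell (median -0.41, camera adjusted p = 0.156). The other 2 lists, of stromal and endothelial markers and of sex-linked genes, had under 4 measured members each, with Pecam1 at -0.65, Stab2 at -0.41 and Xist at 0.04.

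Immediate early genes, which are induced within minutes by stimulation or handling, were lower in vcS5 as well. Of 18 measured, 9 fell and none rose, with a median of -0.79 (camera adjusted p = 4.01e-07, and adjusted p = 0.433 with an estimated correlation). When adjusted over the list alone, 11 fell. Fosb, Egr1, Egr3 and Nr4a1 had log2 changes of -1.45, -1.45, -1.32 and -1.26, beside the median of -1.38 for B cell markers. Interferon response genes had 3 of 21 lower, Oas2 at -1.56, Ifi44 at -1.05 and Oasl2 at -0.95, with a median of -0.27 (camera adjusted p = 0.0363, and adjusted p = 0.668 with an estimated correlation). Adjusted over the list alone, 2 rose and 6 fell, and Ifi44 lost its call with quantile normalization (adjusted p = 0.0557 by limma). The interferon call was lost without wild type replicate 1 (camera adjusted p = 0.112), without vcS5 replicate 1 (0.312, median -0.09), with the filter at a mean FPKM of 5 (0.135, median -0.16) and among protein-coding rows alone (0.0508). Chemokine and homing receptor genes did not pass as a list (median 0.18, camera adjusted p = 0.0723), with 6 of 22 higher and 3 lower, and 10 and 4 when adjusted over the list alone. Without vcS5 replicate 2 this list passed as higher, with a camera adjusted p of 0.0428, and without wild type replicate 2 its median was 0.40. Cxcr3, Ccr2 and Cx3cr1 had log2 changes of 1.94, 1.79 and 1.42.

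**Figure D2:**
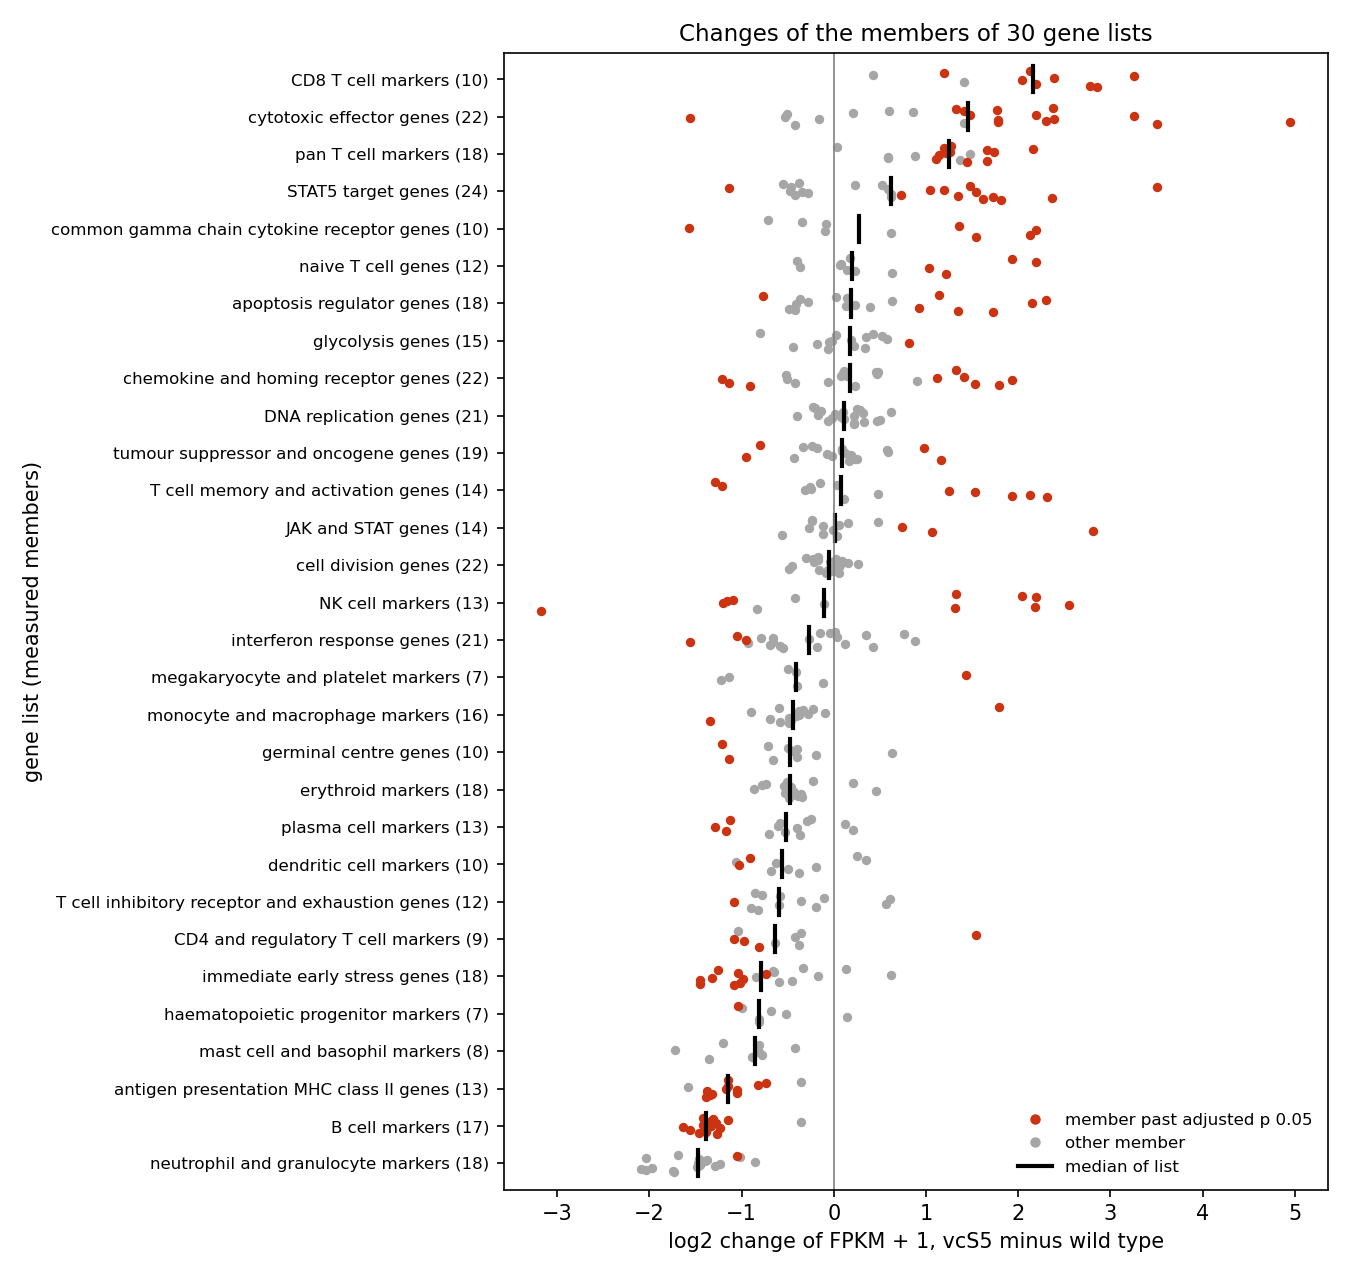
Log2 change of FPKM + 1 (x axis, vcS5 minus wild type) of each measured member of 30 gene lists (y axis, with the number of members), with a black bar at each median. Red points passed an adjusted p of 0.05 by limma, and medians ran from -1.47 for neutrophil and granulocyte markers to 2.16 for CD8 T cell markers.

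By camera 19 of the 30 lists tested passed, 6 as higher and 13 as lower. With an estimated correlation 0 passed, with 2 at an unadjusted p under 0.05. That form of camera rests on 2 residual degrees of freedom, so it had little power whatever the correlation. For the CD8 list the estimate of 0.01 equalled the preset value, yet the adjusted p by camera went from 2.02e-10 to 0.433. The lost call of the CD8 list therefore does not show that correlation accounts for it. Estimates over lists ran from -0.07 for dendritic cell markers to 0.78 for neutrophil and granulocyte markers. They were 0.51 for pan T cell, 0.52 for B cell and 0.44 for MHC class II genes. For lists with estimates far above 0.01, the preset form may give p-values that are too low. Fry tests whether the genes of a list move one way on balance, without reference to other genes. By fry 10 passed, and 24 passed its test for change in either direction. Lists called by camera but not by fry included CD4 and regulatory T (adjusted p = 0.144 by fry), naive T (0.124), plasma cell (0.0928) and interferon (0.211). Others were neutrophil (0.203), monocyte (0.288), mast cell and basophil (0.171), progenitor (0.128), exhaustion (0.112) and immediate early genes (0.0574). The remaining lists that passed by camera also passed by fry. Over the 30 lists 151 member calls were made, against 31 without wild type replicate 1, 53 without wild type replicate 2, 9 without vcS5 replicate 1 and 3 without vcS5 replicate 2. With 2 libraries per group an exact permutation test could not pass 0.05, so the p-values rest on a spread shared across rows. Of the 1241 rows that passed by limma, 899 also had q under 0.05 in the authors' deposited table, all 899 in the same direction, and that table had 1630 such rows, 756 higher and 874 lower.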

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

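Protein-coding rows only, rows with a 0 left out and the q-values of the authors' deposited table were tried after the data had been seen. The count of 1241 rows stayed within 1.5 times, from 932 to 1630, under both pseudocounts, the filter at a mean FPKM of 5, median centring, quantile normalization, no variance trend, receptor segments left out, a minimum of 2-fold and the added settings. At a threshold of 0.01 it was 201. Leaving out 1 library gave 71 to 245 rows, and 19 to 129 protein-coding rows of 900, where fewer samples leave 1 residual degree of freedom and the lone sample is assumed to vary like the other group. Tested alone, protein-coding rows gave 1372 calls, 673 higher and 699 lower, against 469 higher and 431 lower in the main fit, and the cause was not tested. Of the 19 lists that passed, 14 kept their call with the filter at 5, where 3 lost it and 2 were not tested. With an estimated correlation 0 kept it, and 18 or 19 did under the other settings run on lists with all 4 libraries. The list test was not run with receptor segments left out, at a threshold of 0.01, with a minimum of 2-fold or on the deposited q-values. Lists beyond the 19 passed with the filter at 5 (1), without wild type replicate 2 (1) and without vcS5 replicate 2 (2).

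With the replicate number as a replicate block, 1028 rows passed, 579 higher and 449 lower, and 866 were shared with the 1241. The correlation of deviations between same-numbered samples was 0.176, over only 2 pairs, so the numbers are not shown to pair the mice. A block that holds both groups equally cannot change a log2 change, so that of Stat5a was again 2.81, and its call was kept. Under the block 18 of the 19 lists kept their call, all but the apoptosis regulators (camera adjusted p = 0.0749). Of 107 genes past the test that the naming rule takes or that were looked up, 17 lost their call under the block, at adjusted p-values by limma of 0.0504 to 0.0827. These were Fcnb, Trem3, Zbtb7b, Cd4, Cd244, Lyz2, Siglech, Ccr9, Sox4, Ifi44, Oasl2, Id3, Sox13, Klrb1a, Il12rb2, Tyrobp and Fcer1g.

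The log2 change of Stat5a ran from 2.67 to 2.95 over the libraries left out, and that of Stat5b from -0.14 to 0.12. Of the same 107 genes, 13 to 43 kept their call with 1 library left out, 12 kept it in all 4 cases, and none reversed. Genes and lists that had not passed changed sign with 1 library left out, with ranges of -1.24 to 0.27 for Hba-a1, -1.15 to 0.47 for Hba-a2, -1.16 to 0.39 for Hbb-b1, -1.36 to 0.44 for Hbb-b2, -0.36 to 0.19 for Mki67, -0.41 to 0.52 for Top2a, -1.57 to 0.74 for Ighg1, -1.09 to 0.25 for Ighg2c, -0.89 to 0.17 for Ighm, -1.36 to 1.59 for Trac, -1.16 to 0.19 for the erythroid median, -0.14 to 0.06 for the cell division median, -0.43 to 0.21 for the natural killer cell median, -0.02 to 0.30 for the memory and activation median and -0.04 to 0.03 for the JAK and STAT median. Without changing sign, medians ran from 0.04 to 0.22 for DNA replication, 0.09 to 0.28 for glycolysis, -0.59 to -0.23 for megakaryocyte and platelet and 0.04 to 0.11 for tumour suppressor and oncogene genes. Quantile normalization put Trac at -0.14, and the filter at 5 put the natural killer cell median at 0.60 and turned the direction of the tumour suppressor and oncogene list at a median of 0.09, the cause not being tested. The planned setting without a filter equals the reported one, since no row lies below it, and the settings for counts or pooled values were not run. Absolute depth is unknown, so rows with few reads cannot be weighed by their counts.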

Other observations

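The tests in this part were chosen after the results they bear on had been seen, apart from that of beta chain V segment shares, which was written first. The genes named in this paragraph and the next were picked after their values were seen. Receptors of the natural killer gene complex on chromosome 6 moved in both directions. Klrb1a and Klrb1b, of the NKR-P1 family, changed by -1.58 (SE 0.26, adjusted p = 0.0284 by limma) and -1.85 (SE 0.20, adjusted p = 0.0118 by limma), both mean values falling below 1 FPKM in vcS5. Klrb1c, a more abundant member of this family, had means of 12.9 FPKM in wild type and 6.87 FPKM in vcS5. It did not pass (log2 change -0.84, SE 0.21, adjusted p = 0.0757 by limma). Klra5 and Klra10, Ly49 receptor genes, rose from 0.549 ± 0.0971 to 9.18 ± 4.06 FPKM and from 2.03 ± 0.313 to 13.1 ± 0.0108 FPKM (SD, n = 2 each), with reads that this family can share. Outside that complex, Tyrobp (chromosome 7) and Fcer1g (chromosome 1), adaptor chains of activating receptors, fell from 170 ± 40.4 to 74.6 ± 2.22 FPKM and from 117 ± 17.8 to 54.1 ± 7.68 FPKM (SD, n = 2 each). They had 198 and 129 FPKM in wild type replicate 1 and 141 and 104 FPKM in replicate 2. Neutrophil and granulocyte markers, with a median log2 change of -1.47, were also higher in wild type replicate 1. Whether these falls share a source was not tested. Cd163l1 and its neighbour 5830411N06Rik, both scavenger receptor genes known from gamma delta T cells, rose together, the latter from 2.05 ± 0.301 to 43.6 ± 5.54 FPKM (log2 change 3.87, SE 0.17, adjusted p = 8.54e-04 by limma). Sox13, a transcription factor of such cells, rose by 1.33 on the log2 scale (SE 0.21, adjusted p = 0.027 by limma). Receptors for interferon-inducing cytokines and Ifng itself also rose, with log2 changes of 1.98 for Il18rap, 1.44 for Il12rb2 and 1.78 for Ifng. So did the thrombin receptor family members F2rl1 (1.70) and F2rl3 (1.73), beside F2r (3.38).

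Several transcripts without a gene identifier rose strongly. The row with the largest change among them (mm10 chromosome 1, 62819337 to 62834637) begins 69 bases past the locus of Nrp2 and had 0.237 and 0.0577 FPKM in wild type and 12.6 and 13.3 FPKM in vcS5, a log2 change of 3.61, against 1.53 for Nrp2. A pair of neighbouring rows on chromosome 10, at 118502070 to 118513148 and 118514535 to 118556605, lie 56178 and 68643 bases from Ifng and had log2 changes of 3.12 and 3.17. Tcrg-C2, a constant gene of the T cell receptor gamma chain (chromosome 13, 19304677 to 19311304), fell from 765 and 1999 FPKM in wild type to 23.5 and 15.2 FPKM in vcS5 (log2 change -5.96, SE 0.49, adjusted p = 0.00615 by limma). It lost its call without vcS5 replicate 1 (adjusted p = 0.0688 by limma) and without vcS5 replicate 2 (0.0902). Trdj2, a joining segment of the delta chain, had 1158 and 2580 FPKM in wild type and was listed at 0 in both vcS5 libraries.

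A hypothesis that 1 T cell clone dominates a vcS5 spleen was tested on T cell receptor beta chain V segments. The most abundant of 18 measured rows was Trbv13-2 in all 4 libraries, with 25.2% and 24.0% of beta V FPKM in wild type and 21.9% and 26.6% in vcS5. The highest vcS5 share was 1.06 times the highest wild-type share, below the 1.5 times set as the limit. This argues only against a clone whose V row, among the 18 measured, takes more than 26.6% of beta V FPKM in vcS5. Only the top row of each library was compared. A clone with another segment could have grown below that share, and segments outside the 18 rows are not seen. Summed beta V values were 475 and 621 FPKM in wild type and 1286 and 1371 FPKM in vcS5. Smaller clones, or several with different segments, stay open. Among kappa chain V rows, Igkv5-39 took 25.5% and 25.4% in vcS5 against a highest share of 7.98% and 11.3% for any row in wild type, and its own log2 change of 1.82 did not pass (adjusted p = 0.176 by limma).

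T cell and CD8 markers rose while B cell markers fell, which might come from a different makeup of the spleen. A larger share of T cells with an unchanged mix is argued against by Cd8a and Cd4, whose log2 changes differed by 3.67 (95% interval 3.29 to 4.04). A lower share of B cells and nothing else would raise other cell types alike, but the median log2 value of the CD8 list, taken within each library, rose by 2.09 more than that of the CD4 and regulatory T cell list (95% interval 0.89 to 3.28). Such per-library medians differ from the medians of log2 changes per gene given for these lists elsewhere. More CD8 T cells and nothing else would lower the markers of all other cells alike. This stays open, since no difference of the per-library B cell median from that of 7 other lists passed (lowest adjusted p = 0.223 over these lists by t test, with 2 degrees of freedom). The largest change was -1.39 against monocyte and macrophage markers (95% interval -3.76 to 0.98), and for CD4 and regulatory T cell markers it was -1.13 (unadjusted 95% interval -2.21 to -0.06). By means in place of medians the lowest adjusted p was 0.0764. Earlier forms of this test used monocyte and macrophage markers alone, which left it open, and Ncr1, which argued against it but was picked for its fall. Altered expression per cell stays open too, with 8 of 469 protein-coding rows that were higher, Gzmm among them, rising beyond Cd8b1 (log2 change 2.78) by more than 2 SE.

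Rows listed at 0 throughout a group passed the test in 78 of 87 cases. Few reads on short features may account for this, since the median annotated exon length was 110 bases over the 59 such rows with a length, against 3761 bases over the 1015 other called rows with one. A 0 in only 1 library of a group occurred in 0 rows, as would be seen if such rows were missing from the table. That would make the spread within groups look too small for these rows. Trdj2 is one of these rows. The 78 are part of the 1241 rows past the test, and no biological explanation was tested.

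Stat5a rose and Stat5b did not. Stat5a reads counted for Stat5b could only raise Stat5b, so they cannot be why its log2 change was -0.013 (95% interval -0.40 to 0.37). Such reads could hide a fall of Stat5b, which stays open. Stat5b had 24.3 and 23.9 FPKM on average in wild type and vcS5, while Stat5a went from 15.4 to 114 FPKM. These values argue against Stat5b reads counted for Stat5a as the source of its rise. Whether Stat5a rose only because CD8 T cells are more numerous cannot be told apart from a rise per cell by comparison with Cd8b1. The log2 change of Stat5a exceeded that of Cd8b1 by 0.027 (95% interval -0.42 to 0.47), and the table gives no values per cell type. By CD8 T cell number alone Stat5a could rise as far as Cd8b1 only if nearly all wild-type Stat5a came from those cells, which was not tested. Expression from the transgene, which the design names, stays among the open explanations and was not tested.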
